A study of Drosophila melanogaster with 6 samples.

How the data were processed

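The samples were dissected midguts of virgin adult Drosophila melanogaster of the strain w1118, 3 libraries of females and 3 of males, each from 30 midguts of flies aged 15 days and kept at 29 °C with at most 15 flies in a vial. Per the labels' protocols, poly(A)-selected, strand-marking libraries were made from 500 ng of total RNA and sequenced as paired reads of 100 bases; the labels name more than a single model of sequencer. Nothing in the labels says whether the replicates came from separate fly cultures, so p-values measure the spread between these pools of midguts, which may be partly technical.

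The values used are the deposited counts: whole-number counts of reads per gene, not normalized, as the authors made them. Per the submitters' processing notes, TopHat2 2.0.11 and HTSeq were used with genome build dm3; the strand setting of the counting, the treatment of reads that match several places and the annotation release are not given in the sources used here. Because the strand setting is not given, values of genes that overlap another gene on the opposite strand are named as such, and so are near-identical copies; tra, tra2, dsx, msl-3, mAcon1, Mal-A1, Pgk, Lsd-1, Myc, Hsp68, Hsp27, Cyp6d2 and otu also overlap such a gene. The tables held 15682 gene identifiers, of which 3265 had 0 counts in all libraries, and no row without a gene. Symbols came from a current gene name table (15002 identifiers matched, and 3 more through RefSeq synonyms); 677 identifiers, 4.33% to 4.78% of counts, kept no symbol. Chromosome arms and exon overlaps were looked up by identifier in the Ensembl annotation of BDGP6 and no coordinates are given, since the builds differ.

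From these counts the following was computed with R 4.3.3. Genes were kept with filterByExpr by sex (minimum count 10, minimum total 15), libraries were scaled with TMM, and the sexes were compared with the quasi-likelihood test of edgeR 4.0.16 (robust dispersion, model of sex alone, all 6 libraries). A gene counted as higher in a sex at a Benjamini-Hochberg adjusted p under 0.05, two-sided; a test against a 2-fold threshold was made with glmTreat. The biological coefficient of variation was 23.7%. Library totals ranged from 23825935 to 38406746 counts. The counts of replicate pairs differed by far more than sampling noise (chi-square per degree of freedom of at least 29.8), so no library was counted more than once.

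The 36 gene lists (pathways, gene families and markers of cell types and neighbouring tissues), the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members, 32 in all, were tested with camera of limma 3.58.1 on voom weights at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry; p-values were adjusted over the lists. None of the 12 lists called at the preset correlation was called with an estimated correlation. Genes named in the text are all sex determination, dosage compensation and yolk protein genes; among genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the libraries of the sexes, the 10 with the largest fold change in each direction; the 3 tested members of each list with the smallest p; and the 3 most abundant genes of each sex. Genes outside this rule (Mal-B2, Pgk, Amy-p, Amy-d, Ser6, Ser8, LysX, GstO3, Cyp4ae1, Cyp318a1, Cyp6w1, Lsd-1, Npc2e, PGRP-LE, betaTry, Myc, pirk, betaTub85D, Mst98Ca and the accessory gland genes other than EbpIII) were named after their values were seen. Of the tested genes, 26.2% had libraries that did not overlap between the sexes, where chance gives 10%.

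Shares of counts were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1, and X-linked against autosomal calls with Fisher's exact test. Alternatives were RLE size factors, no scaling, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, leaving out marker genes of other tissues, factors from autosomal genes and an adjusted p under 0.01.

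The steps were tested on simulated data drawn from the real means, dispersions and library sizes of the 3 female and 3 male libraries, with 200 of 8941 genes changed. edgeR called 136 genes, 8 of them unchanged ones, and recovered 14% of genes changed by 1.5-fold, 66% at 2-fold, 86% at 4-fold and 90% at 8-fold. With a single shifted list, camera called that list and 0 of the other lists. The simulated genes were drawn independently of each other, whereas the correlation estimated among the real cytosolic ribosomal protein genes was 0.927. The simulation therefore cannot show how often camera calls a list of correlated genes that does not differ.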

Results

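Gene expression was measured by RNA-seq in the dissected midgut, the main digestive and absorptive part of the intestine, of adult Drosophila melanogaster of both sexes. The flies were virgin and 15 days old, of the white-eyed laboratory strain w1118, kept at 29 °C. The 6 libraries were 3 from females and 3 from males, each made from 30 pooled midguts. Counts assigned to genes came to 23825935, 33278485 and 29036334 in female replicates 1 to 3 and to 30600544, 31582128 and 38406746 in male replicates 1 to 3. A count of 3 therefore stood for 0.0781 to 0.126 CPM, the usual unit of counts scaled to library size, a floor that covers counting error only. The question was which genes and gene groups differ in level between the female and the male midgut. Fold changes are given as log2 female over male with a standard error, and levels as mean CPM ± SD over the 3 libraries of a sex. That standard error is the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. It therefore restates the p-value of a gene and is no separate measure of spread.

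The sex-specific RNAs of the dosage compensation machinery separated the libraries by their labelled sex. roX1, a noncoding RNA of the male complex that raises transcription of the X chromosome, stood at 587 ± 111 CPM in males and 0.493 ± 0.287 CPM in females (log2 -10.17 ± 0.36, edgeR adjusted p = 2.7e-07). Its companion RNA roX2 had 1141 counts in the 3 male libraries and 0 in the 3 female libraries, at least 326-fold lower in females against a floor of 3 counts over the group. msl-2, which codes for the subunit of that complex that females do not make, was lower in females (log2 -1.53 ± 0.14, 9.14 ± 0.182 against 26.4 ± 1.89 CPM, edgeR adjusted p = 0.00011). Sxl, the switch gene of female identity, was higher in females (log2 0.71 ± 0.14, 157 ± 4.15 against 96.4 ± 14.2 CPM, edgeR adjusted p = 0.00898). Of the 14 genes of sex determination and dosage compensation, 1 was higher in females, 3 were higher in males and 10 did not pass. Adjusted over the list alone, the counts were 1 and 4, with msl-3 added.

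The other members of that list did not pass over all genes. The transcription factor gene dsx, whose splicing differs between the sexes, stood at 21.9 ± 3.71 CPM in females and 42.7 ± 23.1 CPM in males (edgeR adjusted p = 0.26), and without male replicate 3 its edgeR adjusted p was 0.00289; DESeq2 called it with all libraries (adjusted p = 0.0359), as it did msl-3 (0.0462). msl-3 had a log2 fold change of -0.61 ± 0.19 (edgeR adjusted p = 0.0748; 0.0489 without female replicate 3). The log2 fold changes of tra, tra2, fru, msl-1, mle, mof, ix and her lay between -0.18 and 0.34, none of them past the threshold. As counts are summed over a gene, sex-specific splicing of Sxl, tra, dsx and fru was not measured. The list had a median log2 fold change of -0.09 and a mean of -1.71, a mean carried mostly by the male-specific roX1 and roX2. As a whole the list was not called (camera adjusted p = 0.0563). It was called lower in females without male replicate 3 (camera adjusted p = 0.0146), with a stricter filter of 5 CPM (0.0259) and by fry, which tests whether the genes of a list move one way on balance (0.0252). roX1 overlaps the gene ec on the opposite strand, and the strand setting of the counting is not known. No count fell on the matched genes of the Y-linked list in any library.

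Among 8941 genes tested, 346 were higher in females and 494 were higher in males, 9.39% of the genes together. The genes with the highest CPM coded for digestive enzymes in both sexes. Abundance in CPM is not corrected for transcript length, so ranks among genes are ranks of counts, not of RNA molecules. CG12374, a predicted carboxypeptidase, had the highest mean in females at 35771 ± 1573 CPM against 10090 ± 4900 CPM in males (log2 1.83 ± 0.35, edgeR adjusted p = 0.0101). alphaTry, a trypsin gene, had the highest mean in males at 23886 ± 2734 CPM against 28450 ± 4682 CPM in females, a difference that did not pass (edgeR adjusted p = 0.516). Mal-A1, a maltase gene that overlaps Cyp4e1 on the opposite strand, was higher in males at 22354 ± 2239 against 9798 ± 1716 CPM (log2 -1.19 ± 0.19, edgeR adjusted p = 0.00247). In male replicates 1 and 2 it stood above alphaTry, at 24395 and 22705 against 22528 and 22097 CPM. Jon65Aiv, a serine protease gene, stood at 23511 ± 1298 and 18224 ± 2406 CPM in females and males (edgeR adjusted p = 0.249).

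**Figure D1:**
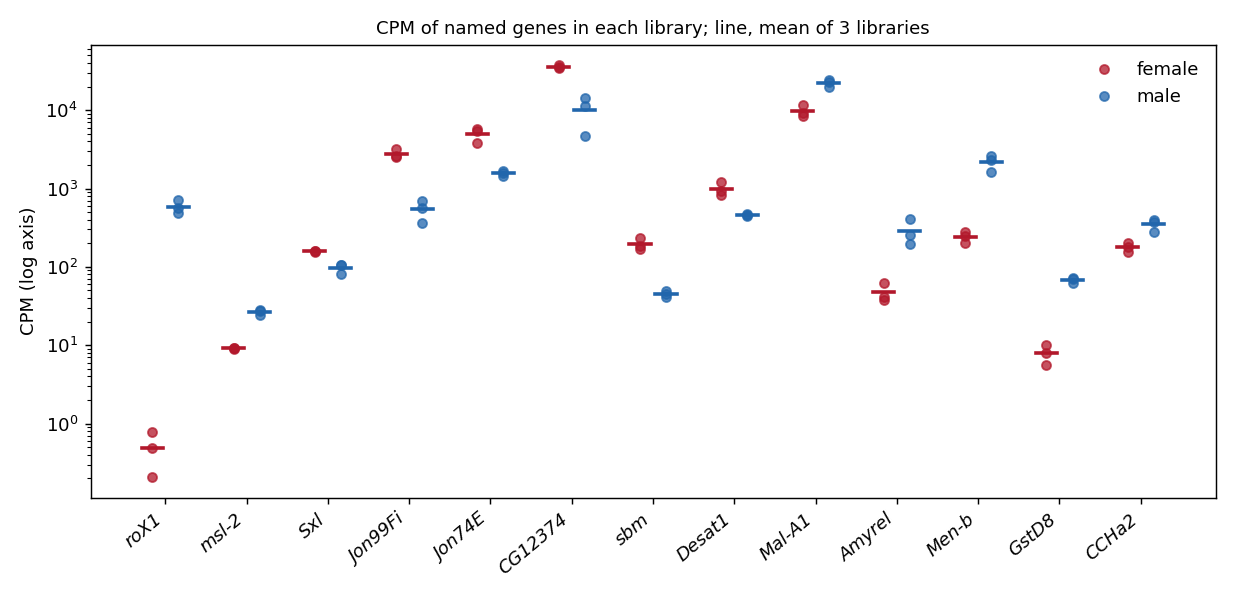
CPM on a log axis for 13 named genes in each of the 3 female and 3 male libraries, with points for libraries and a line for the mean of each sex. The female and the male libraries do not overlap for any of the genes shown, and roX1 spans the widest range, 0.493 CPM in females against 587 CPM in males. All genes shown were called, and some were named by a rule that required no overlap, so the separation follows from their choice.

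The genes with the largest differences toward females included genes for an amino acid transporter, a protease and a transcription factor. CG4991 (FBgn0030817), on the X, was higher in females at 25.1 ± 2.45 against 0.830 ± 0.307 CPM (log2 4.90 ± 0.26, edgeR adjusted p = 6.11e-06). It shares exon sequence with its same-strand neighbour CG16700 (log2 2.02 ± 0.20), so the values of this pair are uncertain. sbm (FBgn0030574), an amino acid transporter gene, was higher in females at 196 ± 34 against 44.9 ± 3.72 CPM. The serine protease gene Jon99Fi (FBgn0039778) was higher in females at 2749 ± 363 against 544 ± 168 CPM, and Plzf, a zinc finger transcription factor gene, at 17.7 ± 2.34 against 3.56 ± 0.839 CPM. The others of the 10 were CG9825, CG14205, CG31041, CG6296 and CG32751, with log2 fold changes of 2.19 to 3.23. Of these, CG32751 lost its call without male replicate 2 (edgeR adjusted p = 0.0642) and with no filter beyond 1 count (0.0554).

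The largest differences toward males, after roX1, included genes for a malic enzyme and for glutathione S-transferases. Men-b (FBgn0029155), which codes for a malic enzyme that makes NADPH, was higher in males at 2172 ± 504 against 242 ± 37.4 CPM (log2 -3.16 ± 0.22, edgeR adjusted p = 2.57e-05). The glutathione S-transferase genes GstD2 and GstD8 were higher in males, GstD8 at 68.4 ± 4.69 against 7.91 ± 2.33 CPM. CG15263 (FBgn0028853) was higher in males at 1537 ± 169 against 106 ± 40.8 CPM. The others were CG42807, CG34040, CG31091, CG13325 and CG34316, with log2 fold changes of -5.38 to -2.90, and CG42807 moved from -4.28 to -4.92 without female replicate 3; CG34316 overlaps an antisense transcript. By the fitted fold, 120 of the genes higher in females and 267 of those higher in males differed by at least 2-fold, and 26 and 58 passed a test against a 2-fold threshold.

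Libraries of the same sex were more alike than libraries of different sexes. Across genes, the correlation of log2 CPM was 0.972 to 0.980 within males, 0.966 to 0.970 within females and 0.953 to 0.961 between the sexes. The first principal component held 41.1% of the variance and parted the sexes, and the second, with 21.2%, set female replicate 2 apart from female replicates 1 and 3. Without female replicate 1 the number of genes higher in females was 171, without female replicate 3 it was 219 and without male replicate 2 it was 164. The count of genes higher in males did not change by over 1.5 times in any fit that left out a single library.

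Carbohydrate-digesting enzymes were lower in females as a group. Of 15 genes tested in the amylase and maltase list, which also holds a trehalase gene, 13 were higher in males. None was higher in females and 2 did not pass. Adjusted over the list alone, 13 were higher in males and 1 in females, Mal-B2 (log2 0.60 ± 0.18). Over all genes Mal-B2 did not pass in edgeR (adjusted p = 0.0647) but did in DESeq2 (adjusted p = 0.0321). The maltase genes Mal-A4 (389 ± 84.7 CPM in females, 2155 ± 476 in males, log2 -2.47 ± 0.22) and Mal-A3 (567 ± 131 against 2152 ± 176 CPM, log2 -1.93 ± 0.19) had the smallest p values, with edgeR adjusted p = 0.000101 and 0.000154. Amyrel, an amylase-related gene that overlaps gprs on the opposite strand, had a log2 fold change of -2.59 ± 0.30. The near-identical amylase copies Amy-p and Amy-d, whose reads cannot be told apart with certainty, had -0.75 ± 0.20 and -0.66 ± 0.18. Both lost their call without female replicate 1 (edgeR adjusted p = 0.181 and 0.194), female replicate 3 (0.155 and 0.174), male replicate 1 (0.0995 and 0.0996) or male replicate 2 (0.0988 and 0.151), and Amy-d also with RLE (0.054). The list was called lower in females (camera adjusted p = 2.55e-11), with adjusted p = 0.312 with an estimated correlation. The list took 3.31% ± 0.496 of counts in females and 7.5% ± 0.823 in males (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Without female replicate 1, 8 of the 15 were higher in males.

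Sugar-consuming pathways ran in the same direction. All 7 tested genes of the pentose phosphate pathway, which makes NADPH and ribose, were higher in males, over all genes and adjusted over the list alone. Examples were Taldo, the transaldolase gene (log2 -1.29 ± 0.17, 193 ± 32.8 against 471 ± 63.9 CPM), Rpi, which overlaps neighbouring genes on both strands (log2 -1.22 ± 0.15), and Pgls (38.8 ± 3.81 against 77.6 ± 4.88 CPM), with edgeR adjusted p of 0.000964, 0.000731 and 0.000919. That list was called lower in females (camera adjusted p = 5.99e-09), with adjusted p = 0.309 with an estimated correlation. Of 12 glycolysis genes, 4 were higher in males over all genes and 10 adjusted over the list alone, and all 12 fold changes were negative. Those 4 were Hex-A, a hexokinase gene (log2 -1.17 ± 0.21), the lactate dehydrogenase gene Ldh (log2 -0.97 ± 0.17), Pgi (log2 -1.49 ± 0.29, edgeR adjusted p = 0.0563 without female replicate 3) and Pgk, which overlaps Cwc25 on the opposite strand. Pgk lost its call without female replicate 1, female replicate 3 or male replicate 1 (edgeR adjusted p = 0.13, 0.106 and 0.0569). Without female replicate 3 the count was 2. The glycolysis list was called lower in females (camera adjusted p = 2.14e-06), with adjusted p = 0.309 with an estimated correlation. Of 14 citrate cycle genes 0 passed in edgeR (4 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom), and the leading member mAcon1 had a log2 fold change of -0.42 ± 0.15 (edgeR adjusted p = 0.132).

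Detoxification genes of the glutathione S-transferase family leaned lower in females, with 33 of 34 fold changes negative. Of 34 tested, 14 were higher in males, 1 was higher in females and 19 did not pass. Adjusted over the list alone the counts were 20 and 1. The gene higher in females was GstO3 (log2 0.55 ± 0.15), which was not called with no scaling beyond the library total (edgeR adjusted p = 0.0586). It also lost its call without female replicates 1, 2 or 3 (0.108, 0.0751 and 0.135) or male replicates 1 or 2 (0.0626 and 0.176). GstD5 (log2 -2.77 ± 0.26, 6.15 ± 2.42 against 42.2 ± 5.56 CPM, edgeR adjusted p = 0.000138) led together with GstD2 (log2 -3.59 ± 0.32) and GstD8 (log2 -3.11 ± 0.21). These neighbours are close paralogs, and reads shared among them could shift single values. As a set they were called lower in females (camera adjusted p = 7.44e-13), with adjusted p = 0.309 with an estimated correlation. Of 72 cytochrome P450 genes, 4 were higher in females and 9 in males (5 and 9 adjusted over the list alone), among them Cyp4d2 (log2 1.37 ± 0.13), Cyp4ae1, Cyp318a1 and Cyp6w1 toward females, and Cyp6g1, which overlaps Cyp6g2 on the opposite strand, and Cyp6d2 toward males (log2 -1.85 ± 0.21 and -1.73 ± 0.19). Cyp318a1 lost its call without female replicate 1 or male replicate 2 (edgeR adjusted p = 0.0761 and 0.0608). Cyp6w1 lost it without female replicates 1 or 2 (0.051 and 0.118), without male replicates 1, 2 or 3 (0.0806, 0.196 and 0.0556, the last with log2 4.81 against 3.93), with no filter beyond 1 count (0.12) and in limma-voom (0.147). The P450 list was not called (camera adjusted p = 0.147), but was called lower in females without female replicate 2 or male replicate 2 (0.0154 and 0.0297). Of 14 redox genes, Prx2, a peroxiredoxin gene, was higher in males (log2 -0.82 ± 0.18, edgeR adjusted p = 0.0149), a call that was lost without female replicate 1, female replicate 3 or male replicate 2 (edgeR adjusted p = 0.0798, 0.057 and 0.0785).

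Serine proteases of the trypsin and Jonah families were higher in females as a group. Of 29 tested, 12 were higher in females, 2 were higher in males and 15 did not pass, and adjusted over the list alone the counts were 17 and 4. Jon99Fi (log2 2.34 ± 0.24, edgeR adjusted p = 0.000174), Jon74E (log2 1.68 ± 0.19, 4996 ± 1070 against 1562 ± 114 CPM, edgeR adjusted p = 0.000403) and Jon65Aii (log2 1.46 ± 0.18, edgeR adjusted p = 0.0007) led toward females. The 2 genes higher in males were Ser8 and Ser6 (log2 -1.45 ± 0.18 and -0.89 ± 0.19). Ser6 lost its call without female replicate 1 or 3 (edgeR adjusted p = 0.0691 and 0.0625). The list was called higher in females (camera adjusted p = 9.49e-09), with adjusted p = 0.312 with an estimated correlation. It took 15.2% ± 0.626 of counts in females and 11.4% ± 1.06 in males (SD, n = 3 each, exact two-sided permutation p = 0.1). Without male replicate 2, 7 of the 29 were higher in females, and 8 without female replicate 1 and without female replicate 3. Several members, alphaTry and betaTry among them, are near-identical copies whose values are uncertain.

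Transcripts of cytosolic ribosomal proteins leaned higher in females. All 79 tested cytosolic ribosomal protein genes had positive fold changes, with a median log2 of 0.64; 33 were higher in females and 0 in males over all genes, and 66 adjusted over the list alone. RpS3A (log2 0.86 ± 0.16, 2120 ± 228 against 1168 ± 116 CPM), RpL27, which overlaps Idh3g on the opposite strand (log2 0.83 ± 0.15), and RpL7-like, which shares exon sequence with CG34164 (log2 0.89 ± 0.17), had the smallest p values, with edgeR adjusted p of 0.00635, 0.00489 and 0.0065. The list was called higher in females (camera adjusted p = 9.99e-31), with adjusted p = 0.4 with an estimated correlation, and fry did not call it (adjusted p = 0.0635). The list took 9.37% ± 0.642 of counts in females and 6.25% ± 1.21 in males (SD, n = 3 each, exact two-sided permutation p = 0.1), with 7.64% in male replicate 3. The number of members higher in females depended on the libraries, with 11, 9 and 16 without female replicate 1, 2 and 3, and 20, 3 and 74 without male replicate 1, 2 and 3. Of 70 mitochondrial ribosomal protein genes 0 passed in edgeR (1 at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom), with a median log2 of 0.03 (camera adjusted p = 0.283). That list was called higher in females without female replicate 3 or male replicate 3 (camera adjusted p = 0.00837 and 0.000011).

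**Figure D2:**
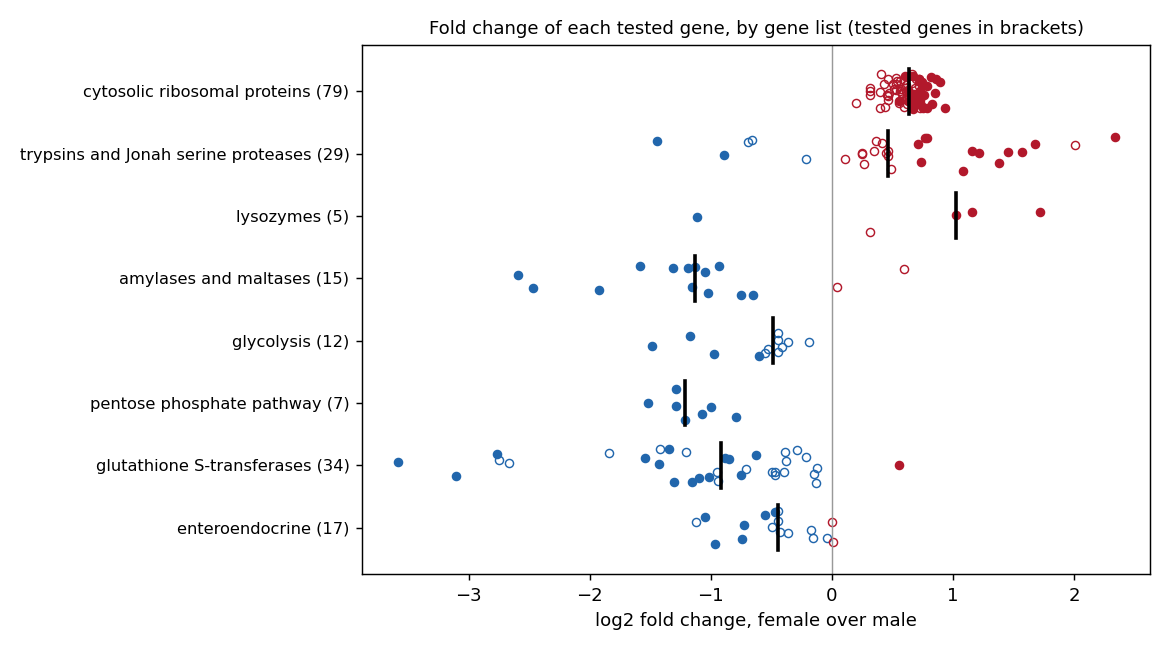
Log2 fold change, female over male, of each tested gene in 8 gene lists; filled points had an edgeR adjusted p under 0.05, open points did not, and the black line is the list's median. All 79 ribosomal protein genes lie above 0, and 13 of the 15 genes of the amylase and maltase list lie below it.

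**Figure D3:**
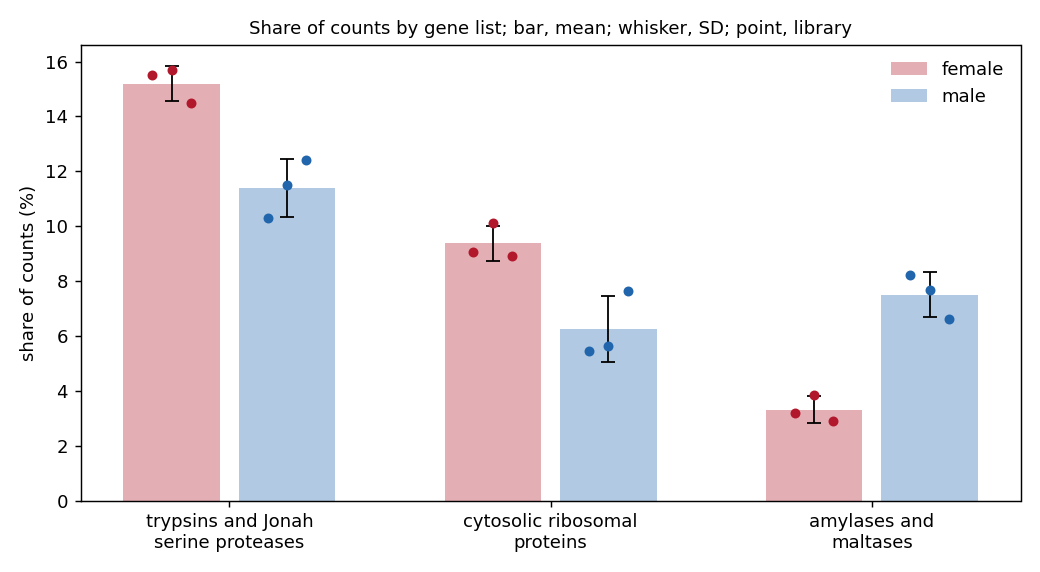
Percent of counts taken by 3 gene lists in each library, with bars for the mean of 3 libraries, whiskers for the SD and points for libraries. The amylase and maltase list, which also holds a trehalase gene, took 3.31% in females and 7.5% in males, and the trypsin and Jonah genes 15.2% and 11.4%.

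Immune and stress genes differed in part. Of 13 tested genes of the antimicrobial peptide and Imd regulator list, 6 were higher in males and 0 in females (7 and 1, PGRP-LE, adjusted over the list alone). PGRP-LE was also called over all genes without male replicate 1 (edgeR adjusted p = 0.0375) and in DESeq2 (0.0338). PGRP-SC1a and PGRP-LB, which code for peptidoglycan-degrading amidases that dampen the Imd pathway, had log2 fold changes of -1.29 ± 0.16 and -1.28 ± 0.18 (edgeR adjusted p = 0.000731 and 0.00122); PGRP-SC1a has a close copy, PGRP-SC1b. The antimicrobial peptide gene AttD had 159 counts in males and 1 in females, a ratio of 136 with a 95% exact counting interval of 24.1 to 5410 (edgeR log2 -6.59, and -8.59 without female replicate 3); the interval covers counting error only, not the spread between pools of midguts. The immune list was called lower in females (camera adjusted p = 0.000738), with adjusted p = 0.309 with an estimated correlation. Lysozyme genes were mostly higher in females: of 5 tested, LysB, LysD and LysE were higher in females (log2 1.02 ± 0.15, 1.16 ± 0.20 and 1.72 ± 0.30) and LysX was higher in males, with the same counts adjusted over the list alone. LysE lost its call without male replicate 1 (edgeR adjusted p = 0.0646), and LysX without female replicate 1, female replicate 2 or male replicate 1 (0.0883, 0.061 and 0.0687). These genes are near-identical copies, and LysD overlaps LysC. The lysozyme list was called higher in females (camera adjusted p = 0.0136), with adjusted p = 0.309 with an estimated correlation, and was not called with no filter beyond 1 count. Of 7 heat shock genes, Hsp68, Hsp23 and Hsp27 were higher in males at low levels (log2 -2.15 ± 0.38, -3.12 ± 0.56 and -1.47 ± 0.30), 3 also adjusted over the list alone; Hsp27 lost its call without male replicate 2 (edgeR adjusted p = 0.0587). The heat shock list was called lower in females (camera adjusted p = 0.00838), with adjusted p = 0.309 with an estimated correlation, and was likewise not called with that filter.

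Some hormone genes of enteroendocrine cells, the secretory cells of the gut epithelium, differed between the sexes. Of 17 markers tested, 6 were higher in males and 0 in females (8 and 0 adjusted over the list alone). The peptide hormone genes CCHa2 (log2 -0.97 ± 0.18, 178 ± 24.2 against 348 ± 65 CPM, edgeR adjusted p = 0.00553) and ITP (log2 -1.05 ± 0.21, edgeR adjusted p = 0.0107) led, and ITP overlaps another gene on the opposite strand. Tk, the tachykinin gene, had 97.3 ± 5.32 against 135 ± 8.56 CPM (log2 -0.47 ± 0.12, edgeR adjusted p = 0.0335), a call lost without any single library except male replicate 3 (edgeR adjusted p = 0.0641 to 0.157). The hormone cell markers as a set were called lower in females (camera adjusted p = 0.000119), with adjusted p = 0.309 with an estimated correlation. The number of members higher in males was 2 without female replicate 1, female replicate 3, male replicate 1 or male replicate 2.

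Markers of stem cells and enteroblasts, the progenitor cells of the epithelium, were not called as a list (camera adjusted p = 0.175). Of 11, cv-2 and Delta, the Notch ligand gene of stem cells, were higher in males (log2 -0.90 ± 0.20 and -1.03 ± 0.27, edgeR adjusted p = 0.0151 and 0.04), 2 also adjusted over the list alone. Delta lost its call without each library in turn (edgeR adjusted p = 0.0621 to 0.115). Of 50 cell cycle genes, BubR1 and RnrS were higher in males (log2 -1.74 ± 0.38 and -0.76 ± 0.21, edgeR adjusted p = 0.0151 and 0.0494), 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.11; 0.0112, lower in females, without female replicate 3). BubR1 and RnrS lost the call without male replicate 2 (edgeR adjusted p = 0.0563 and 0.0586) and without male replicate 3 (0.0688 and 0.0888); RnrS also lost it without each female replicate (0.0995 to 0.186) and with RLE normalization (0.0564) and limma-voom (0.053). Enterocyte markers had 0 of 8 genes past the threshold in edgeR (1 at an unadjusted p under 0.05, 0 in DESeq2 and limma-voom, camera adjusted p = 0.922), with a log2 fold change of -0.34 ± 0.14 for Myo31DF. Midgut region markers had 0 of 7 in edgeR (2 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom, 2 adjusted over the list alone, camera adjusted p = 0.0563), with log2 fold changes of 0.56 ± 0.17 for lab and 0.46 ± 0.14 for bab2. lab was called without female replicate 2 (log2 0.71, edgeR adjusted p = 0.0221) and with no filter beyond 1 count (0.0486). The region list was called higher in females without female replicate 2, male replicate 1 or male replicate 2 (camera adjusted p = 0.0206, 0.0262 and 0.0417) and with no filter beyond 1 count (0.0272).

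Few lipid, hormone and signalling genes passed. In the lipid digestion and storage list, 3 of 17 genes were higher in females and 2 in males (5 and 4 adjusted over the list alone). The desaturase gene Desat1 at 988 ± 204 against 462 ± 17.6 CPM (edgeR adjusted p = 0.00274), Lsd-1 and Npc2e were higher in females. Lsd-1, which overlaps CG10214 on the opposite strand, lost its call without female replicate 2 (edgeR adjusted p = 0.0516), and Npc2e without female replicate 3 or male replicate 3 (0.0749 and 0.0593). The gene mdy, which codes for an enzyme of triglyceride synthesis, and ATPCL, the citrate lyase gene, were higher in males (log2 -1.72 ± 0.22 and -1.45 ± 0.28). ATPCL overlaps other genes and lost its call without female replicate 3 (edgeR adjusted p = 0.0554). The list's median was -0.08 and its mean -0.30 while its test pointed up (camera adjusted p = 0.639). Of 13 genes of ecdysone and juvenile hormone signalling, the juvenile hormone receptor genes gce and Met were higher in females (log2 1.39 ± 0.14 and 0.54 ± 0.13, edgeR adjusted p = 0.000142 and 0.0277), 2 also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0563). It was called higher in females without female replicate 2, male replicate 1 or male replicate 2 (camera adjusted p = 0.0166, 0.0166 and 0.0377) and with no filter beyond 1 count (0.0192). Met lost its call without female replicate 1, female replicate 3, male replicate 2 or male replicate 3 (edgeR adjusted p = 0.0644 to 0.114) and with no scaling (0.0722). In insulin signalling 0 of 10 genes passed in edgeR (2 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom, 1 in each direction adjusted over the list alone, camera adjusted p = 0.505), with log2 fold changes of -0.50 ± 0.15 for Pi3K21B and 2.02 ± 0.62 for Ilp3. edgeR called Pi3K21B without male replicate 3 (adjusted p = 0.0147), with no scaling (0.0412) and with the other filters (0.0491 and 0.0435). It called Thor without male replicate 1 (log2 0.96, adjusted p = 0.005) and Ilp3 without female replicate 2 (0.0413). Without male replicate 2, Ilp3 moved to log2 2.62 and was not called (edgeR adjusted p = 0.0635). The list of JAK-STAT, EGFR, Wnt, Dpp and JNK pathway genes had 0 of 11 past the threshold in edgeR (0 at an unadjusted p under 0.05, in DESeq2 and in limma-voom, camera adjusted p = 0.792), with Socs36E at -0.43 ± 0.21. Of 18 V-ATPase subunit genes, Vha100-2 was higher in males (log2 -0.56 ± 0.14, edgeR adjusted p = 0.0255), a call lost without each of the 3 female replicates or male replicate 2 (0.0744 to 0.12). The list was not called (camera adjusted p = 0.286). The redox and citrate cycle lists were not called either (camera adjusted p = 0.159 and 0.547). The citrate cycle list had a median of 0.01 while its mean and test pointed down.

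Some markers of other tissues were uneven among libraries. The yolk protein genes Yp1, Yp2 and Yp3, products of female fat body and ovary, had log2 fold changes of 5.32 ± 1.86, 5.23 ± 1.70 and 3.71 ± 0.90 but did not pass over all genes (edgeR adjusted p = 0.219, 0.184 and 0.0824), and 3 of 3 passed adjusted over the list alone. DESeq2 called Yp1 and Yp3 (adjusted p = 0.0231 and 0.00013). edgeR called Yp3 without female replicate 1 (log2 2.54, adjusted p = 0.0032) and without female replicate 3 (log2 4.12, adjusted p = 0.0423). Yp1 counts were 3493, 761 and 682 in female replicates 1 to 3 and 3, 155 and 2 in male replicates 1 to 3. The yolk protein list was called higher in females (camera adjusted p = 0.0204), with adjusted p = 0.461 with an estimated correlation, and was not called without male replicate 1 or male replicate 3 (0.0634 and 0.0658) or by fry (0.216). EbpIII, of the accessory gland and ejaculatory duct list, had 249, 1029 and 126 counts in female replicates 1 to 3 and 548, 205 and 680 in male replicates 1 to 3. Male replicate 3 held 3104 counts on 16 accessory gland and ejaculatory duct genes that had 0 in male replicates 1 and 2, and 7042 counts on the oenocyte gene Cyp4g1 against 10 and 89 in male replicates 1 and 2 (edgeR adjusted p = 0.379 between the sexes). Of 19 testis genes, 14 had counts in males and 0 in females, with 4, 29 and 273 counts in male replicates 1 to 3. Of these, 9 had counts in male replicate 3 alone, betaTub85D at 85 and Mst98Ca at 33 among them. Without male replicate 3 and female replicate 1, the latter the highest in yolk protein counts, a fit chosen after seeing the data called 266 genes higher in females and 402 higher in males.

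Of 9 Malpighian tubule markers, Oatp58Da, an anion transporter gene, was higher in males (log2 -0.68 ± 0.15, edgeR adjusted p = 0.0159), a call lost without female replicate 2, female replicate 3 or male replicate 2 (0.0635, 0.0646 and 0.0766). That list was called lower in females (camera adjusted p = 0.0297), with adjusted p = 0.312 with an estimated correlation, and was not called without female replicate 3 or male replicate 3 (0.222 and 0.0658), with no scaling (0.0545), with either of the other filters (0.073 and 0.0865) or by fry (0.072). The scavenger receptor gene crq, which overlaps ex, was the 1 of 4 haemocyte markers higher in males (log2 -1.15 ± 0.17; list, camera adjusted p = 0.159, called lower in females by fry at 0.0252), and Appl the 1 of 6 neuronal markers (log2 -0.84 ± 0.18, edgeR adjusted p = 0.0649 without female replicate 1 and 0.0599 without male replicate 2; list, camera adjusted p = 0.479). In the visceral muscle, trachea, fat body and oenocyte, and testis lists 0 of 13, 4, 4 and 3 tested genes passed in edgeR (camera adjusted p = 0.175, 0.876, 0.547 and 0.967). The muscle list was called lower in females without female replicate 1 or male replicate 3 (camera adjusted p = 0.00153 and 0.00899). At an unadjusted p under 0.05 there were 2 muscle genes and 0 in the other lists. The testis list had a median of -0.03 while its camera test pointed up. DESeq2 called 2 muscle genes and limma-voom 0, and with neither tool did the other lists hold a call. Fewer than 3 genes were tested in the hindgut, ovary and accessory gland lists, where otu was higher in males at 8.16 ± 3.91 against 3.33 ± 0.355 CPM (edgeR adjusted p = 0.0437; 0.0953 to 0.214 without any single library except male replicate 1; limma-voom adjusted p = 0.137) and the hindgut gene byn stood at 0.682 ± 0.955 CPM in females and 1.45 ± 0.209 in males (log2 -1.11, edgeR adjusted p = 0.578). Without female replicate 1, byn was called lower in females (log2 -3.40, edgeR adjusted p = 0.0351).

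Genes of the X chromosome were shifted slightly toward females. The median log2 fold change was 0.05 over 1432 X-linked genes and -0.03 over 7069 genes of the 2L, 2R, 3L and 3R arms. Of the X-linked genes, 80 (5.59%) were higher in females, among them Sxl, sbm, gce and Cyp4d2, against 252 (3.56%) on these arms, an odds ratio of 1.6 (95% interval 1.22 to 2.08, two-sided Fisher's exact test adjusted p = 0.00166). For genes higher in males the shares were 4.82% and 5.76% (odds ratio 0.829, 0.628 to 1.08, adjusted p = 0.199). As a set, X-linked genes were not called with the preset correlation (camera adjusted p = 0.135) and were called higher in females with an estimated one (adjusted p = 0.0199); genes of the other 5 arms were not called. Genes are not independent units, so Fisher's test overstates its certainty.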

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

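The fit without male replicate 3 and female replicate 1 was chosen after seeing the data; all other alternatives were planned. With RLE or no scaling, with each filter and with each test, more genes were higher in males than in females, and between 650 (replicate block) and 840 (DESeq2) of the 840 called genes kept their call and direction when all libraries were used. DESeq2 called 552 genes higher in females against 346 in edgeR. In the simulation, 19 of the 154 genes that DESeq2 called were unchanged ones (12.3%), against 5.88% for edgeR and 4.65% for limma-voom. Genes called by DESeq2 alone may thus hold more false calls. At an adjusted p under 0.01 the counts were 136 and 276, by construction smaller. limma-voom passed 15 genes higher in females and 35 higher in males against the 2-fold threshold, compared with 26 and 58; the cause was not tested. Leaving out each library in turn gave 164 to 419 genes higher in females and 332 to 513 higher in males, and without male replicate 1 the split was 50.2% toward females, compared with 41.2% with all libraries; with fewer libraries the test has fewer degrees of freedom. With no scaling 35.1% of the calls were toward females. Of the lists, 4 were called higher and 8 lower in females. An estimated correlation left 0 and 0, and fry called 2 higher and 9 lower. With fry the Malpighian tubule, cytosolic ribosomal protein and yolk protein lists were lost, and the haemocyte and sex determination lists were gained. Lists not called with all libraries were called in some alternatives, up to 3 in a fit without 1 library. Without male replicate 3 and female replicate 1 the gained lists were mitochondrial ribosomal proteins, sex determination and visceral muscle (camera adjusted p = 0.00004, 0.00904 and 0.00000167). The set tests already rest on voom, so limma-voom was not run for them. The X odds ratio stayed at 1.54 to 1.84 without each library. The X minus autosome median was 0.078 with all libraries and 0.073 to 0.093 without each library. It was 0.093 without male replicate 3 alone and 0.096 without male replicate 3 and female replicate 1. Both of these shifts were larger than the SD between replicates of 0.009. Of 70 called genes named by the rule, 54 kept their call in each refit that gave a value, 52 of these also passed an adjusted p under 0.01, and none reversed. The rule mostly picks genes with small p values or large separated differences, which favours stable calls. Of all 840 called genes, 467 (without female replicate 1) to 707 (without male replicate 3) kept their call and direction when a single library was left out. No sign of pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.117, -0.199 and -0.099, and no library correlated best with its own number. The deviations were taken from the mean of each sex, so these correlations constrain one another. They cannot exclude a shared culture or day. With a replicate block 261 and 415 genes were called, the X odds ratio was 1.68, and Met, Vha100-2, Delta, Tk, GstO3, Pgk, Amy-p, Amy-d, Cyp6w1 and the Malpighian tubule list were not called; 17 ribosomal protein genes and 4 enteroendocrine markers were, as was the sex determination list (camera adjusted p = 0.0378). Of 50 genes with a simulated 1.5-fold change 7 were recovered.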

Other observations

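The tests of stem cell and ovary markers and of accessory gland genes below were chosen only after the result was seen. Some genes outside the naming rule, chosen after their values were seen, are of interest. Myc, the growth regulator gene on the X, which overlaps CG12535 on the opposite strand, was higher in females at 205 ± 26.6 against 55.4 ± 12.3 CPM (SD, n = 3 each, log2 1.89 ± 0.18, edgeR adjusted p = 0.000126). pirk, an inhibitor of the Imd pathway, was higher in males at 126 ± 23.4 against 22.3 ± 12.1 CPM (log2 -2.49 ± 0.38, edgeR adjusted p = 0.00774; 0.0515 without male replicate 1). The lipid droplet gene Lsd-1 was higher in females (log2 0.98 ± 0.20, edgeR adjusted p = 0.0119; 0.0516 without female replicate 2).

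With 10 splits of the 6 libraries into 3 and 3, the share of splits cannot be under 0.1, so the splits are too few. In each of 4 results 1 split, the real one, reached the real value. The number of called genes was 840 for the sexes and at most 1 for another split, and the number past the 2-fold threshold was 84 and at most 1. The number of lists called by camera at the preset correlation was 12 for the sexes and up to 11 for another split, so such list calls also arise between libraries of mixed sex. Every other split is unbalanced in sex, however, so its list calls and X difference can hold part of the sex difference. Sex also widens the spread within mixed groups, which lowers their gene calls. The other splits are therefore not comparisons free of sex. The absolute X minus autosome difference in median log2 fold change was 0.078 for the sexes and at most 0.052 for another split.

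Cytosolic ribosomal protein genes had a median log2 fold change of 0.64 toward females. Other genes matched on exon length and mean expression reached at most 0.246 in 1000 draws, with a median draw of -0.028. This argues against length or expression level as the whole cause. The match in level was incomplete, however, with a median log2 CPM of 9.91 in the list and 9.54 in the matched genes. The draws also ignored the correlation among ribosomal protein genes, so their spread is too narrow. Stem cell and enteroblast markers had an upper quartile of -0.037, below the ribosomal median. Ovary and eggshell genes took at most 0.000603% of counts in a female library against up to 0.00134% in a male library. The stem cell and enteroblast values argue against a larger share of progenitor RNA in the female libraries. The ovary shares do not decide on ovary RNA, since otu alone held most of that list's counts. That gene had 281 counts in females and 847 in males. The yolk protein genes, products of female fat body and ovary, went the other way, higher in each female library than in each male library. Cell numbers were not measured, so more progenitor cells are not excluded. The sex of the flies and GC content stay open and untested.

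X-linked genes leaned to females, and each female library lay above each male library in its X minus autosome median (0.038 to 0.046 against -0.053 to -0.029). Autosomal genes matched on length and mean expression reached a median of at most -0.011 in 1000 draws, below the X median of 0.05, which argues against length or expression level as the cause. Sex itself stays open, since X dose and sex cannot be separated in this design, and the shift is small, 0.078 on the log2 scale.

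Male replicate 3 held transcripts of accessory gland genes that male replicates 1 and 2 lacked, though the most abundant gene of the list, EbpIII, was found in each library and had the most counts (1029) in female replicate 2. Of 21 listed genes, 16 had 3 or more counts there and 0 in male replicates 1 and 2, led by Acp36DE (513 counts), Mst57Db (344) and Mst57Da (321). A trace of accessory gland tissue would give this pattern. The list was fixed before the data were examined, but this count restates the observation that prompted it and is no independent test. The whole list came to 106 CPM in male replicate 3 and at most 32.6 CPM in another library, and 19 of its genes had their highest CPM in male replicate 3, which argues against reads from another library of this series. The oenocyte gene Cyp4g1, at 7042 counts there, and 9 testis genes with counts in that library alone are open as signs of further carried-over tissue. No biological explanation was tested, since a single library shows it.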
